A study of Mus musculus with 2 samples.

How the data were processed

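Circular chromosome conformation capture with sequencing (4C-seq) had been applied to F1 hybrid mouse trophoblast stem cells, per the labels. This assay cuts crosslinked chromatin with a restriction enzyme, joins the cut ends, and sequences what became joined to 1 chosen fragment, the viewpoint. The labels give 1 group of 2 biological replicates at passages 15 to 20 and name 8 anchor points. Lists for 7 promoter viewpoints were used, each with 1 list for the active X (Xa) and 1 for the inactive X (Xi), giving 14 lists; the remaining anchor point was not analysed here. No reads or counts were used.

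Each deposited list gives, per the file headers, the chromosome, start and end of a contacted region, a class (cis, trans or no call) and the parental allele contacted (Cast, B6 or no call). The lists hold no value per region and no replicate column, so the depth is unknown and no replicate error can be computed. CASAVA 1.8 and Bowtie 0.12.7 are listed in the submitters' processing notes, with the mm9 build and no roles stated. The way contacts were called, the threshold and the way the 2 replicates were combined are not given in the sources used here. On the X, the word trans was read as a contact with the other homologue, since cis contacts were always Cast in the Xa lists and always B6 in the Xi lists. Most contacts carried no allele call.

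Positions were compared with the NCBIM37 genome, the same assembly as mm9, and with the GENCODE vM1 annotation. The lists count from 0 with both ends included, so 1 was added to both. Of the 8336 regions, 97.7% started and 98.0% ended at a restriction site. The sites were BglII for Ftx and Huwe1 and HindIII for the other 5 viewpoints, and 0% of starts lay at the other enzyme's site. Single fragments made up 27.8% to 57.7% of the regions of a list; the others were runs of neighbouring fragments. The 4 regions that start at base 1 of a chromosome were left out of the autosomal gene density. Old gene names were updated through synonyms of a RefSeq table of assembly GRCm38, from which no coordinate was taken. The RefSeq name Ftx stands for B230206F22Rik in the annotation, and Jpx for Enox. Gpr173 has 2 annotation entries, which were counted separately in counts of annotated genes and once in gene lists.

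The viewpoint was the unit of comparison. Differences between Xi and Xa were averaged over the 7 viewpoints, as log2 ratios or percentage points, and tested with a two-sided exact sign-flip permutation test over 128 sign patterns, whose smallest possible p is 0.0156. With 6 viewpoints it is 0.0312. Viewpoints are not biological replicates: they came from the same cells, and Taf1 and Ogt, Ftx and Rlim, and Huwe1 and Kdm5c are neighbours. Such a p describes how uniform a difference was over these 7 promoters, not how it would vary between cultures. Sign-flip tests of 9 main measures were adjusted together by the Benjamini-Hochberg method, and the other sign-flip tests were not adjusted. The 5 that passed all lay at the smallest possible p. All of these but the overlap between homologues were chosen after the data were seen. They draw in part on the same contacts, and the adjusted p of each depends on the others. Overlap between lists (at least 1 bp) was compared with 1000 circular shifts of 1 list along the X, two-sided, with the same adjustment. Shifting keeps the spacing of contacts but not their decay with distance from the viewpoint. Shares have 95% Wilson intervals in the tables; intervals cover counting error only.

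The counts of contacts, their reach, the share within 1 Mb, the overlap tests, 5 gene lists and the rule for naming were fixed before the data were examined. The rule named the 7 viewpoint genes. It also named, per list, the nearest contact outside 50 kb, the farthest on each side, and the 3 longest merged regions (gap of up to 50 kb) with no contact of the other homologue within 100 kb. A few of these are described and the rest summarised. Of the list genes, 11 of 13 were found for the X-inactivation centre (Linx was not found, and Cnbp2 is the same gene as Zcchc13), 15 of 15 for escape genes, and 12 of 12 for the Kdm5c and Huwe1 neighbours. For the Ogt and Taf1 neighbours 18 of 19 were found (not Gcna), and for the Nkap neighbours 13 of 14 (not Rhox5). Chosen after the data were seen were the length covered within 1 Mb, the protein-coding genes within 1 Mb, the merged block around each viewpoint, the share of contacts on the X, transcription start sites (TSS) per Mb beyond 5 Mb, and the test of list genes beyond 5 Mb. No number was added to TSS numbers, except 0.5 for cis-called or uncalled contacts alone, where some numbers are 0, in 1 alternative for all contacts, and in simulated lists. A comparison of contact strength had been planned and could not be made without values per region.

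Alternatives were other windows, merging, other overlap rules, cis-called or uncalled contacts alone, and leaving out each viewpoint. The statistics were tested on simulated lists. With equal numbers of contacts, 5% of 100 simulated sets passed the threshold, and with a ratio of 0.75 100% did. Every simulated viewpoint was given the same ratio, whereas real ratios differed between viewpoints, so the 100% does not carry over to the real lists. With 0% of Xi contacts copied from Xa, 1.02% of 98 simulated list pairs passed, and with 10% copied 100% did. Simulated contacts on the X were placed at random along it, without crowding near the viewpoint. This rate therefore does not cover real lists, in which contacts of both homologues crowd around the same promoter. With 10% of Xa contacts placed on a TSS, 89% of 100 sets passed in the test of TSS density. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.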

Results

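Contacts of 7 X-linked promoters were listed separately for the active and the inactive X in mouse trophoblast stem cells, the stem cells of the placental lineage. The cells came from a cross of the Cast/EiJ and C57B6/N strains, so that sequence differences tell the homologues apart. The series asks how genes that escape X inactivation are arranged in space. In mm9, Nkap lies on X from 34666790 to 34690741, Taf1 from 98728073 to 98797128, and Ogt from 98835399 to 98879690. Ftx lies from 100756246 to 100819093, Rlim from 101152502 to 101176623, Huwe1 from 148235350 to 148369960, and Kdm5c from 148667563 to 148709078. Taf1 encodes a subunit of the general transcription factor TFIID, Ogt the O-GlcNAc transferase, and Huwe1 a ubiquitin ligase. Ftx is a long noncoding RNA gene of the X-inactivation centre, Rlim encodes a ubiquitin ligase that promotes Xist expression, and Kdm5c encodes a histone demethylase and is a known escape gene.

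The 14 lists held 8336 contacts, 4200 for the active X and 4136 for the inactive X. Of these, 1187 and 1052 lay on the X. Lists ranged from 57 contacts for Nkap on the inactive X to 2502 for Ftx on the inactive X, so small lists such as those of Nkap carry less precision. Both replicates were combined in each list, without values per region. No replicate error exists for any value below, and the spread given is that between promoters. Every cis-called contact was Cast on the active X and B6 on the inactive X, so the state of the X and the strain cannot be told apart in any comparison here.

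The inactive X had the shorter list for 6 of 7 promoters. Nkap had 75 contacts on the active X and 57 on the inactive X, Rlim 218 and 167, Taf1 462 and 407, Huwe1 387 and 350, and Kdm5c 253 and 221. Ogt differed by little, with 435 and 432, and Ftx had more on the inactive X, 2370 and 2502. The mean log2 ratio of inactive to active was -0.18 ± 0.18 (SD, n = 7 viewpoints), or 0.885-fold, with an exact sign-flip p of 0.0469 and an adjusted p of 0.0703 over 9 tests. The mean log2 ratio was -0.32 for contacts on the X (exact p = 0.0469) and -0.021 for autosomal contacts (exact p = 0.672). When neighbouring regions were merged, the ratio was -0.090 and no longer passed the threshold (exact p = 0.125). It also missed the threshold when any 1 promoter other than Ftx was left out, with exact p values of up to 0.0938. The share of listed contacts on the X differed by -4.54 ± 5.95 percentage points (SD, n = 7 viewpoints; exact p = 0.109, adjusted p = 0.141). This is the direct test between the X and the autosomes, and it missed the threshold.

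Less of the X within 1 Mb of each promoter was in contact on the inactive X, in all 7 cases. Huwe1 contacts covered 892 kb of the surrounding sequence within 1 Mb on the active X and 331 kb on the inactive X. Nkap contacts covered 650 and 339 kb, Kdm5c 900 and 530 kb, Rlim 1369 and 907 kb, and Taf1 1234 and 937 kb. The smallest differences were those of Ogt, 1399 and 1288 kb, and Ftx, 1456 and 1336 kb. The mean log2 ratio was -0.62 ± 0.47 (SD, n = 7 viewpoints), or 0.649-fold, with an exact sign-flip p of 0.0156, the smallest the test can give, and an adjusted p of 0.0281. This measure was chosen after the data were seen. Within 500 kb the ratio was -0.37 (exact p = 0.0781) and Taf1 turned, with 676 and 770 kb; within 2 Mb Ogt turned, with 1720 and 1729 kb. Divided by the length in autosomal contacts, the ratio was -0.43 and missed the threshold (exact p = 0.0938), with Ogt and Rlim above 0.

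**Figure D1:**
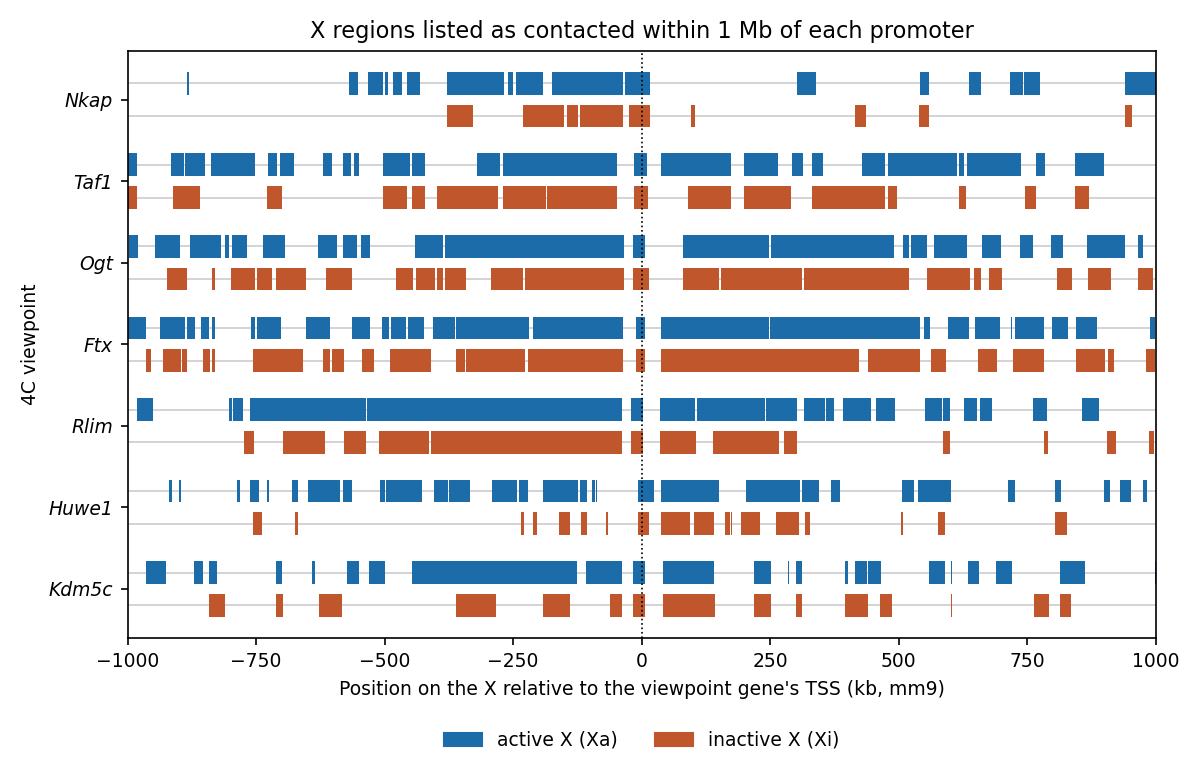
Map of the X sequence listed as contacted within 1 Mb on each side of the 7 viewpoint genes, with the position relative to the viewpoint's transcription start site in kb (mm9) on the horizontal axis and the viewpoints from low to high coordinates down the vertical axis. Blue bars are merged contacts of the active X and orange bars those of the inactive X; around Huwe1 they cover 892 kb and 331 kb.

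Genes next to the promoters followed the same division. Of 189 pairs of a viewpoint and a protein-coding gene within 1 Mb, 135 were overlapped by contacts of the active X and 103 by those of the inactive X. The pairs include the viewpoint's own gene where it is protein-coding, which was overlapped on both homologues. These counts come from the same contacts as the covered length and are not separate evidence. Huwe1 reached 14 of 18 genes on the active X and 7 on the inactive X, with Iqsec2, Tspyl2, Fam120c and Gnl3l among those listed for the active X alone. Taf1 reached 30 of 33 and 22, again with some, such as Foxo4, Pin4 and Rps4x, on the active X alone. Ogt reached 28 of 28 and 26, and Ftx 18 of 20 and 17. The mean difference was -17.0 ± 11.6 percentage points (SD, n = 7 viewpoints), lower in 7 of 7, with an exact sign-flip p of 0.0156 and an adjusted p of 0.0281. Around Nkap 37 of 59 genes were reached on neither homologue; most of them are Rhox homeobox genes, a cluster of close copies in which read placement is uncertain.

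The merged block of contacts around a promoter, which bridges gaps of up to 50 kb, differed in its extent between homologues. Around Kdm5c it ran for 589 kb on the active X, from Huwe1 through Smc1a and Iqsec2 past Gpr173. On the inactive X it ran for 204 kb, from Iqsec2 past Gpr173. Kdm5c contacts of the inactive X also overlapped Huwe1 and Smc1a, but beyond a gap of more than 50 kb. Smc1a encodes a cohesin subunit. Around Ftx the block measured 1645 kb on the active X and 1347 kb on the inactive X, where it lacked Abcb7, Uprt and 1700031F05Rik. Of these, Abcb7 and Uprt were overlapped by Ftx contacts of the inactive X outside the block, and 1700031F05Rik was not. Around Rlim it measured 1297 and 999 kb, and on both homologues it held Xist, Tsix, Jpx and Ftx. Huwe1 went the other way, with 157 kb on the active X and 334 kb on the inactive X, where the block also held Hsd17b10, Ribc1 and Smc1a. Huwe1 contacts of the active X overlapped these genes too, outside the block. That block ended 151 kb from the TSS and the next contact began at 203 kb, a gap just over the limit. The direction for Huwe1 therefore depends on the limit of 50 kb. That for Ftx can turn with the limit too. Its block on the inactive X ended 591 kb from the TSS at higher coordinates. Further contacts followed there from 654 to 999 kb, across gaps not far above the limit. On the active X the Ftx block ended at 886 kb and the next contact began at 989 kb. These block lengths were not tested.

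The gene lists fixed beforehand gave the following counts near their own promoters, with the viewpoint's own gene included where it is on the list. In the X-inactivation centre, Ftx contacts overlapped 11 of 11 genes on both homologues, and Rlim contacts 11 on the active X and 10 on the inactive X, without Nap1l2. Xist, the RNA that coats the inactive X, lay in Ftx, Rlim and Ogt contacts of both homologues. Among the 12 genes around Kdm5c and Huwe1, Kdm5c contacts overlapped 12 and 9 and Huwe1 contacts 11 and 6. The Kdm5c gene itself lay in Huwe1 contacts of neither homologue. Among the 18 genes around Ogt and Taf1, Ogt contacts overlapped 18 and 17, Taf1 contacts 17 and 13, Ftx contacts 12 and 12, and Rlim contacts 13 and 6. Med12, Nlgn3 and Cxcr3 were among those listed for Rlim on the active X alone. Among the 13 genes around Nkap, Nkap contacts overlapped 6 and 5.

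In these lists, promoters far apart on the X reached each other's neighbourhoods mainly from the active X. Most contacts beyond 5 Mb carried no allele call, so the homologue of the contacted gene is unknown for them. Taf1, 49940 kb from Kdm5c, was in contact with Kdm5c, Smc1a, Iqsec2, Phf8 and Fam120c on the active X and with none of the 12 genes of that list on the inactive X. In the other direction Kdm5c was in contact with Taf1, Nono, Zmym3, Hdac8 and Phka1, and Huwe1 with Ogt, Nono, Snx12, Hdac8 and Cited1, in both cases with 0 of 18 list genes on the inactive X. Huwe1 also reached Ftx and Rlim on the active X alone. Ftx contacts overlapped 8 genes of the Kdm5c and Huwe1 list on the active X and 5 on the inactive X, and Huwe1 and Fam120c were the 2 genes found on both. Over the 4 neighbourhood lists and all genes beyond 5 Mb of a viewpoint, 45 of 225 gene and viewpoint pairs were in contact on the active X and 8 on the inactive X.

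This difference averaged -17.9 ± 9.11 percentage points (SD, n = 7 viewpoints) and was lower in 7 of 7, with an exact sign-flip p of 0.0156 and an adjusted p of 0.0281. By list, 19 and 6 of 60 pairs were in contact for the Kdm5c and Huwe1 neighbours, 12 and 1 of 54 for the Ogt and Taf1 neighbours, 12 and 1 of 78 for the Nkap neighbours, and 2 and 0 of 33 for the X-inactivation centre. Over all protein-coding X genes beyond 5 Mb, 7.46% of pairs were in contact on the active X and 4.45% on the inactive X. The listed neighbourhoods fell by 14.9 percentage points beyond that general difference (exact sign-flip p = 0.0156). They started from 20% on the active X, so part of the larger fall in points may follow from the higher start. The lists were not matched to all genes for gene density, and neighbouring genes under 1 contact count as separate pairs. The lists had been fixed beforehand and this test was chosen afterwards. With cis-called contacts alone the difference was -5.02 points and missed the threshold (exact p = 0.0625). With uncalled contacts alone it was -13.8 points (exact p = 0.0156).

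**Figure D2:**
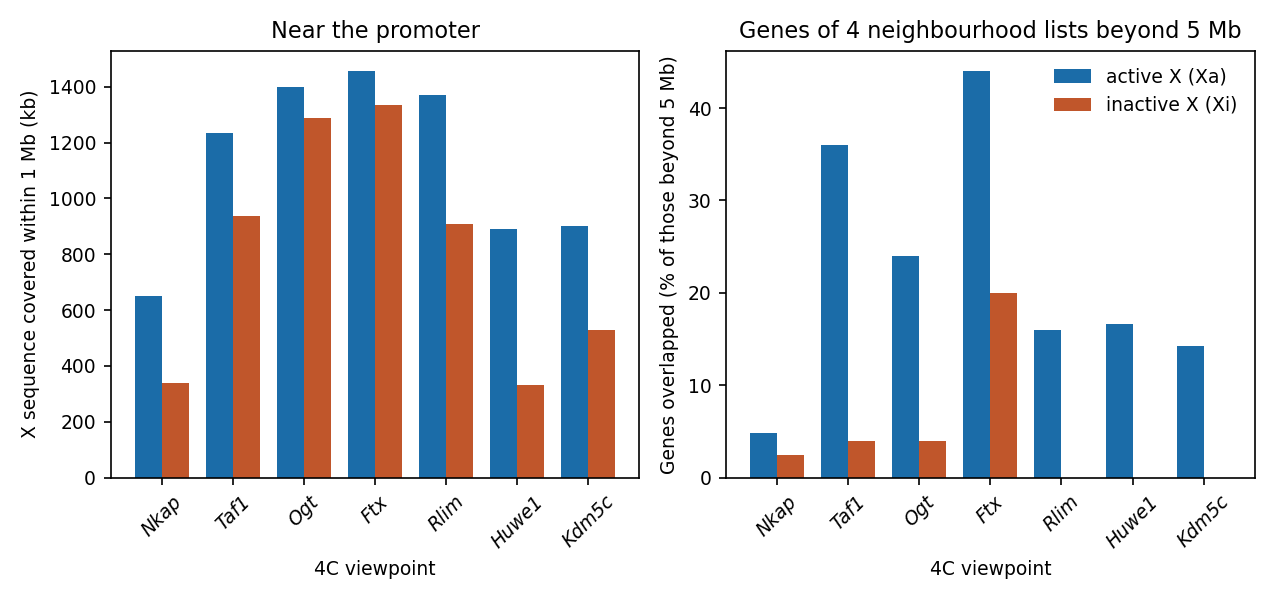
Bars for each of the 7 viewpoints on the active X (blue) and the inactive X (orange): on the left the X sequence covered by contacts within 1 Mb in kb, on the right the percent of genes of 4 neighbourhood lists beyond 5 Mb that contacts overlapped. All 7 viewpoints were lower on the inactive X in both panels, and Rlim, Huwe1 and Kdm5c had 0 such genes there. Each bar is 1 value from 1 list, so no error bar exists.

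Far contacts of the active X were also richer in promoters. Beyond 5 Mb, the density of protein-coding TSS in Ogt contacts was 33.0 per Mb on the active X and 9.79 per Mb on the inactive X, and in Ftx contacts 12.6 and 4.84 per Mb. The average of the X was 5.75 per Mb. Kdm5c had 21.9 and 9.15 per Mb, and Rlim 17.6 and 6.45 per Mb. Nkap differed least, with 22.5 and 20.0 per Mb, but these rest on 8 and 3 TSS. Compared within 4 classes of region length, Nkap had 26.3 and 12.2 per Mb. The inactive-X densities of Rlim and Huwe1 also rest on 3 TSS each. Without such classes, the mean log2 ratio over the viewpoints was -1.17 ± 0.50 (SD, n = 7 viewpoints), lower in 7 of 7, with an exact sign-flip p of 0.0156 and an adjusted p of 0.0281. This measure was chosen after the data were seen, and with cis-called contacts alone and 0.5 added to each TSS number the ratio was -0.60 (exact p = 0.281), against -1.08 for all contacts in that form. Nkap, Huwe1 and Kdm5c were then higher on the inactive X, Huwe1 only through the 0.5, since its 3 cis-called contacts there held 0 TSS. Uncalled contacts alone, in the same form, gave -1.24 (exact p = 0.0156). The autosomal contacts of the inactive-X lists also held fewer TSS per Mb, with a mean log2 ratio of -0.52, lower in 7 of 7 (exact p = 0.0156).

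Known escape genes had similar counts on both homologues. Of 83 pairs of a viewpoint and an escape gene beyond 5 Mb, 9 were in contact on the active X and 10 on the inactive X. Counting near genes and the viewpoint's own gene too, Ftx contacts overlapped 7 of 15 escape genes on the active X and 9 on the inactive X. There Kdm5c, Ddx3x and Car5b were added and Kdm6a was absent. Rlim contacts overlapped 6 and 3, Kdm5c contacts 3 and 2, Ogt contacts 4 and 5, Taf1 contacts 4 and 4, Huwe1 contacts 1 and 1, and Nkap contacts 0 and 0. The difference between escape genes and the other lists was not tested.

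The share of X contacts within 1 Mb did not pass its test between the homologues. It was 42.3% on the active X and 31.2% on the inactive X for Nkap, 24.8% and 21.1% for Kdm5c, and 6.72% and 6.20% for Ftx. Rlim was the exception in direction, with 17.0% and 19.1%. The mean difference was -2.79 ± 4.25 percentage points (SD, n = 7 viewpoints; exact sign-flip p = 0.125, adjusted p = 0.141). Within 500 kb the mean turned to 1.45 points (exact p = 0.125). Within 1 Mb it was -3.61 points without Rlim (exact p = 0.0312) and -1.41 points without Nkap (exact p = 0.25).

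Promoters had contacts far along the X on both homologues, and Rlim contacts on the inactive X ran from 12450316 to 159067692. The farthest contacts at high coordinates lay at Mid1, an escape gene close to the pseudoautosomal boundary, for Taf1, Ftx and Kdm5c on both homologues and for Rlim on the active X. At low coordinates the farthest contacts of Nkap, Rlim and Huwe1 on the active X lay at Clcn5. The median distance of X contacts from Ftx was 26.7 Mb on the active X and 27.6 Mb on the inactive X, and from Ogt 22.3 and 12.3 Mb. The mean log2 ratio was 0.22 ± 1.47 (SD, n = 7 viewpoints; exact sign-flip p = 0.953). This mean rested on Nkap, whose median was 1.33 Mb on the active X and 14.3 Mb on the inactive X, the latter from 32 X contacts; without Nkap the ratio was -0.32 (exact p = 0.125).

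The regions contacted by a promoter were shared in part between homologues. Of the Nkap contacts of the inactive X, 38.5% overlapped a contact of the active X, against 1.63% after circular shifts. The share was 34.4% for Rlim, 33.7% for Kdm5c, 27.9% for Huwe1, 24.0% for Taf1, 22.0% for Ogt and 19.7% for Ftx. The mean excess over shifted positions was 24.7 ± 9.29 percentage points (SD, n = 7 viewpoints; exact sign-flip p = 0.0156), and 7 of 7 viewpoints passed at an adjusted p under the threshold of 0.05. Both lists crowd around the same promoter and the shifts do not keep this, so an excess was likely from the start. Contacts near the viewpoint accounted for most of the excess: beyond 5 Mb its mean was 4.10 points (exact p = 0.0312). There only Kdm5c passed alone, with 14.8% against 1.45% (adjusted circular-shift permutation p = 0.0140), while Nkap shared 0%.

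Neighbouring promoters shared more contacted sequence on the active X by the Jaccard index, but no pair passed the test. Taf1 and Ogt, 107 kb apart, had an index (shared over total length) of 0.238 on the active X and 0.144 on the inactive X. Ftx and Rlim, 358 kb apart, had 0.171 and 0.101, and Huwe1 and Kdm5c, 432 kb apart, had 0.141 and 0.0521. Relative to shifted positions, the overlap was higher on the active X in 4 of the 7 nearer pairs, such as Taf1 and Ogt with 7.64 and 5.08 times, and on the inactive X in 3, such as Huwe1 and Kdm5c with 7.45 and 7.56 times. For the distant pair Ogt and Kdm5c the index was 0.0456 and 0.00176, and the overlap 2.96 and 0.559 times that of shifted positions. Over the 14 pairs more than 40 Mb apart the median was 2.42 and 1.20 times. In the circular-shift test 0 of 21 pairs passed on either homologue after Benjamini-Hochberg adjustment over 42 tests, with a smallest adjusted p of 0.0629. The smallest permutation p of 0.00200 would become 0.0839 for a pair that reached it alone, so a single pair could not pass. At an unadjusted permutation p under 0.05, 6 pairs passed on the active X and 7 on the inactive X. The difference between the homologues was not tested for these pairs.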

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

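The tests of the B6 share below were chosen after the values had been seen; that of the overlap with cis contacts was set before its result was seen.

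The lists also hold contacts with the other X homologue, which were separated above only where cis-called contacts alone are given. There were 30 in the active-X lists and 33 in the inactive-X lists, or 6.90% and 9.97% of the X contacts with an allele call. Such contacts lay within 1 Mb of the viewpoint in 43.3% of cases on the active X and 42.4% on the inactive X, against 26.9% and 28.5% of cis contacts, differences that missed the threshold (Fisher's exact p = 0.0600 and 0.110). Of the 63 together, 58.7% overlapped a cis contact of the same list, against 2.39% after circular shifts (two-sided permutation p = 0.00200, the smallest that 1000 shifts can give). Some of these are the same region listed under both classes, as the promoter's own region is for Nkap on both homologues. The shifts also do not keep the nearness of both classes to the viewpoint. This p therefore cannot decide whether calls were wrong, and a wrong allele call in part of the reads stays possible. The region of the Kdm5c promoter itself is listed for the active X only as a contact with the other homologue. No biological explanation was tested, and contact between the homologues stays open.

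Among autosomal contacts with an allele call, 58.7% were B6 in the inactive-X lists and 52.6% in the active-X lists (Fisher's exact p = 0.0137 over pooled contacts, which are not independent). This difference rested on Ftx, with 59.8% and 51.6%. Without Ftx the shares were 56.3% and 54.2% (Fisher's exact p = 0.672). The mean difference over the 7 viewpoints went the other way, at -3.60 points (exact sign-flip p = 0.625), though 4 of 7 were higher in the inactive-X lists.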

How the results depend on the processing

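Alternatives with autosomes, cis-called contacts or contacts beyond 5 Mb were chosen after seeing the data. So were those with repeated positions counted once, the length covered on the X and the span of contacts. The same holds for all alternatives of measures chosen after the data were seen. Over 114 alternatives, 93 kept the result, 17 kept the direction but missed the threshold, 1 newly passed it and 3 turned the direction. Of the 93, 28 left out 1 viewpoint of measures whose 7 differences have 1 sign; their p is then fixed at 0.0312 and says nothing about stability. Another 6 are numbers of viewpoint pairs that passed, 0 in each, which have no direction and say nothing about stability either. The mean log2 ratio of contact numbers was -0.090 after merging and -0.021 on autosomes, neither past the threshold, and between -0.22 and -0.14 with 1 viewpoint left out. The share within 1 Mb turned to 1.45 points within 500 kb, and lay between -3.61 (without Rlim, where it passed) and -1.41 points with 1 viewpoint left out. The log2 ratio of the reach lay between -0.32 (without Nkap, which turned it) and 0.40. The log2 ratio of length covered was -0.37 within 500 kb and -0.43 when divided by the length in autosomal contacts, and no longer passed in either. With cis-called contacts alone, TSS density (-0.60, against -1.08 for all contacts with the same 0.5 added) and list genes beyond 5 Mb (-5.02 points) no longer passed. With uncalled contacts alone both passed, at -1.24 with the same 0.5 added and at -13.8 points. The lists of cis-called contacts are shorter, but whether that is the reason was not tested. Beyond 5 Mb, the overlap between homologues turned to -0.346 points for Nkap and passed alone only for Kdm5c. The cause of the other changes was not tested either. Alternatives that need a value per region (the stronger contacts, weighted distances, contact strength with its filters, pseudocounts, count models and replicate settings) could not be run. No paired analysis was possible because the lists combine both replicates. Depth is unknown, so lists of different length cannot be brought to 1 depth.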

Other observations

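The count of intergenic regions, the stretch around Flna, the tests on length within 1 Mb, the Dxz4 locus, TSS density at like region lengths and the autosomes were chosen after the data were seen; the other tests on TSS density and those on escape genes were set before their own results were seen.

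The longest regions contacted on 1 homologue alone differed in their gene content. Of the 21 named for the active X, 21 overlapped genes, with 70 gene overlaps under the contacts themselves, while of the 21 named for the inactive X 11 did, with 19 gene overlaps, and 10 were intergenic. More of them were intergenic on the inactive X for 6 of 7 viewpoints (exact sign-flip p = 0.0312). The regions were not matched for length, and longer regions can overlap genes more often. The longest was longer on the active X except for Ftx and Ogt. For Nkap it measured 91.4 kb on the active X and 20.4 kb on the inactive X, for Ftx 97.9 and 125 kb. Those of the inactive X included an intergenic region of 125 kb for Ftx, from 112439497 to 112564112, 417 kb from Ube2dnl2. Contacts covered 35.2 kb of it, and the rest was bridged gaps. Another was a region of 105 kb at Spin4 for Rlim, of which contacts covered 83.4 kb.

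A gene-dense stretch of the X, from 70798821 to 71619372 with 35 protein-coding genes, held 1 of these active-X regions for 6 of 7 viewpoints and none for the inactive X. Ogt contacts there held Flna, Emd and Gdi1 on the active X, Rlim contacts L1cam, Naa10 and Hcfc1, Kdm5c contacts Atp6ap1, Plxna3 and Ubl4a, and Taf1 contacts Hcfc1 and Irak1. Flna encodes the actin crosslinker filamin A and Hcfc1 a transcriptional coregulator. Ogt contacts covered 168 kb of the stretch on the active X and 13.4 kb on the inactive X, Ftx contacts 198 and 35.3 kb, and Rlim contacts 96.8 and 0 kb. Nkap had no contact there on either homologue. The stretch was picked from these contacts, so no test was made on it.

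Less X sequence within 1 Mb of the promoters was listed on the inactive X. Fewer reads assigned to that homologue may account for it. The log2 ratio of the length near the promoter minus that of the length in autosomal contacts was -0.43, below 0 in 5 of 7 viewpoints and not in Ogt and Rlim (exact sign-flip p = 0.0938), so this stays open. Against the number of autosomal contacts it was -0.60 (exact sign-flip p = 0.0156), but that sets a length against a count. Easier mapping of B6 reads to the reference would raise the inactive X, which is the B6 chromosome, whereas the ratio was -0.62. A difference between the Cast and B6 chromosomes cannot be told apart from the state of the X, since 0 crosses of the other direction were in the labels. A difference between the active and the inactive X therefore remains 1 of the open explanations.

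Far contacts of the inactive X held fewer protein-coding TSS. A general bias of those lists towards gene-poor sequence may account for it, since autosomal contacts differed the same way. The log2 ratio on the X minus that on the autosomes was -0.64 and missed the threshold (exact sign-flip p = 0.0781, below 0 in 6 of 7 viewpoints); without Nkap it was -0.87 (exact sign-flip p = 0.0312). A few gene clusters had been predicted to leave the share of far contacts with a TSS level. It was 20.4% on the active X and 8.84% on the inactive X, a mean difference of -11.6 points (exact sign-flip p = 0.0156). A few contacts dense in TSS would not alone give this. Clusters reached by many contacts on the active X alone would also raise the share, so this test cannot exclude them. Longer regions on the active X would leave the density level between regions of like length, yet compared within 4 classes of region length the log2 ratio was -1.29 (exact sign-flip p = 0.0156). Gene clusters, the general bias, the strain difference and a difference between the active and the inactive X stay open.

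Other hypotheses gave no decision. Escape genes may lie together on the inactive X: far contacts there overlapped escape genes 10 times, against 4.13 after circular shifts (two-sided permutation p = 0.0120). On the active X the number was 9 against 4.39 (two-sided permutation p = 0.0659). These numbers sum over all 7 viewpoints, of which only Ftx and Kdm5c are on the escape list. Ftx gave 4 of the overlaps on the inactive X and 2 on the active X, and Kdm5c 1 and 2. The sums therefore cannot show whether escape genes contact each other. Random lists of X genes of like length averaged 5.44 overlaps on the inactive X and had fewer than observed in 94.6% of 10000 draws. Their 95% range of 1 to 10 held the observed number, so genes in general may give the same count. On the active X random lists averaged 8.68 overlaps, against the 9 observed. Across the 4933407K13Rik locus, which holds the Dxz4 repeat, from 72952271 to 73010038, the share of far contacts differed by 2.39 ± 17.1 points (SD, n = 7 viewpoints; exact sign-flip p = 0.875). It was lower on the inactive X in 4 of 7, and without Nkap the mean turned to -3.57 points (exact sign-flip p = 0.281). Contacts per Mb and gene density over the 19 autosomes had a Spearman rho of 0.316 (permutation p = 0.188) and a Pearson r of 0.470 (permutation p = 0.0474). Without the 2 chromosomes farthest from the median gene density r was 0.176 and rho 0.218. Of the autosomes left out singly, chromosome 11 moved r most, to 0.138, while r was 0.584 without chromosome 7, so the Pearson value rests on chromosome 11. That chromosome had 5.07 contacts per Mb over the lists of both homologues. The next highest was chromosome 17 with 2.76 per Mb.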
